A study of Xenopus laevis with 20 samples.

How the data were processed

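Whole embryos of the African clawed frog Xenopus laevis were measured at stage 13, the early neurula, on 20 single-colour Affymetrix Xenopus laevis arrays. Per the labels, 10 arrays held uninjected siblings (replicates 1 to 10) and 5 held embryos injected with synthetic mRNA of Xrx1. This homeobox transcription factor gene, now named rax, acts in the eye field. The other 5 held embryos injected with MoXrx1, an antisense morpholino oligonucleotide against it. Per the labels, every injected embryo also received mRNA of green fluorescent protein (GFP) as a tracer, and both dorsal blastomeres were injected at the 4-cell stage. Each array held RNA of 3 embryos per the labels, while the series design text speaks of RNA extracted from single embryos. The doses differ between the labels: 50 pg or 50 ng of Xrx1 mRNA, 400 pg or 400 ng of GFP mRNA, and 1 pM, 10 pg or 0.5 pmol of morpholino. Nothing in the labels says whether embryos of different arrays came from different parents, so p-values measure the spread between these arrays.

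The deposited values are on the log2 scale, with 1 value for each of 15611 probe sets in each array. They were made with GCRMA, per the submitters' processing notes; its version, the number of runs and the arrays normalized together are not given in the sources used here. The deposited values ran from 0.749 to 15.4, none was missing, and no 2 arrays of a group were alike beyond a correlation of 0.99. Arrays have no read depth; their number limits the precision.

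The 120 control probe sets were left out of the tests, and a probe set was kept when its log2 value was above 4 in at least 5 arrays, which left 10435. Gene symbols came from the platform annotation, updated through a gene table for 2 symbols. Of the 15491 gene probe sets, 9304 had 1 symbol, 195 had several and 5992 had none, and none was named from several symbols. The endings .L and .S of a symbol name the homeologous copies of a gene in this allotetraploid frog. A gene with several probe sets was represented by the probe set with the highest mean over all arrays; where probe sets of a named gene disagreed, each is given.

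Group differences were tested per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 group means over all 20 arrays) with the Benjamini-Hochberg adjustment and a threshold of 0.05, and a probe set past it is said to be called. Adjusted p-values below are limma's unless another test is named, and ± gives the SD over arrays for a level and the SE of the fit for a log2 difference. Gene lists were tested with camera in limma with a preset inter-gene correlation of 0.01, adjusted over the 27 lists, and again with an estimated correlation. The lists were eye field; anterior neural plate and forebrain; midbrain, hindbrain and posterior neural; pan-neural and neural plate progenitor; proneural and neuronal differentiation; Notch pathway; neural crest; preplacodal ectoderm; cement gland and hatching gland; epidermis; multiciliated cells; BMP signalling and ventral; organizer and axial mesoderm; paraxial mesoderm and muscle; endoderm; blood and endothelium; pluripotency and early embryo; Wnt pathway; FGF and ERK pathway; Hedgehog pathway; retinoic acid pathway; cell cycle; p53 targets; innate immune response; stress response; ribosomal proteins; and genes tied to Rx1 in earlier work. The symbol pattern of the ribosomal list also took 5 S6 kinase genes. Without them its camera adjusted p was 1.24e-14 for mRNA against all controls. Some lists share genes. All measured genes tied to Rx1 in earlier work but tle2.L are also in another list, with otx2, pax6 and six3 in eye field.

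The groups, the tests, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule named rax; the 10 higher and 10 lower genes with the largest change among called probe sets with an informative symbol whose injected arrays all lay on 1 side of the control mean; for each list up to 4 called members with the smallest adjusted p, or the 1 member with the smallest if none was called; up to 10 genes called in opposite directions and up to 10 in the same direction by both injections; and, between the injections, the 5 higher and 5 lower genes. Only some of the genes taken by the list part of the rule are printed.

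Replicate numbers are shared by the groups. After removal of group means, mRNA arrays and the controls of the same number (1 to 5) correlated across probe sets at 0.26 to 0.51, over 0.1 in 5 of 5 pairs, and 4 of the 5 mRNA arrays correlated best with the control of their own number, so the numbers were taken to pair these arrays. Arrays labelled morpholino correlated with controls 1 to 5 of the same number at -0.088 to 0.28. Of these pairs 3 of 5 were over 0.1, and 4 of the 5 arrays correlated best with their own number, which fell short of the rule that every pair be over 0.1. With controls 6 to 10 in order they correlated at -0.19 to 0.043, 0 of 5 over 0.1. Out of order, the best control of that set correlated at 0.27 to 0.55 with each of them (morpholino 3 with control 9 at 0.55), but no label ties them so. Arrays labelled morpholino were therefore not paired, except in the alternative with the replicate number as a block. The paired fit of mRNA arrays against controls 1 to 5, with the number as a block, was added after the data had been seen. So was a fit with the array set as a block, where the first set is mRNA 1 to 5 with controls 1 to 5 and the second is morpholino 1 to 5 with controls 6 to 10. The sets are not in the labels. They were drawn from the deposited values, whose 75th percentile was 8.03 to 8.10 in the first set and 8.13 to 8.15 in the second.

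The fits named in this paragraph, and no others, were tested on simulated normal values with the real means and residual SDs of the 10435 probe sets. In each 200 were changed. Values were drawn independently per probe set, so probe sets that vary together were not simulated. False calls numbered 8 to 14 in a fit, with 14 among 174 calls for mRNA against morpholino. Changes of 1 on the log2 scale were recovered for 78% (mRNA against control), 75% (morpholino against control), 65% (mRNA against morpholino), 84% (paired) and 68% (morpholino against controls 6 to 10) of the changed probe sets, and changes of 2 for 97%, 99%, 95%, 96% and 95%.

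Alternatives were no filter, a stricter filter (above 6), quantile normalization, median centring (largest shift of an array 0.126), a variance trend with robust fitting, array weights, only the compared groups, the replicate number as a block, controls 1 to 5 or 6 to 10 alone, and each array left out in turn. Added later were the paired and set-block fits, the set block with 4 axes of variation among controls as covariates in 2 constructions, and fits without arrays whose tracer signal went against their label. A simulation of unchanged groups with the difference between the sets, and splits within the first set, were added last. So were lower bounds for those of the 5 higher and 5 lower genes between the injections with a group mean under log2 4. That level is the filter's and no measured detection limit. Apart from the paired fit and its version without the block, fits with controls 1 to 5 or 6 to 10 alone kept all injected arrays. No array was moved to another group.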

Results

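Gene expression was compared at the start of neurulation, when the eye field forms, between 10 arrays labelled uninjected control, 5 labelled Xrx1 mRNA injected and 5 labelled Xrx1 morpholino injected. The comparisons ask which transcripts change when Xrx1 is in excess in dorsal blastomeres, which change when its translation is blocked, and whether the injections move genes in opposite directions.

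The injected tracer gives a check of the labels. The array carries 120 control probe sets, and the 2 with the largest range over the arrays were AFFX-Xl-AF292560-1_s_at and AFFX-Xl-M62653-1_s_at. They were at 13.1 to 14.5 in mRNA arrays 1 to 5 and at 2.81 to 3.56 in controls 1 to 5. They are called tracer probe sets here because they were high in the arrays of this set labelled as GFP-injected and low in its uninjected arrays. The gene tables name no transcript for them. The second name carries the identifier of a jellyfish GFP mRNA record, from general knowledge not checked here. In the second set the signal went against 8 of 10 labels. It was high in the arrays labelled control 6, 7, 8 and 9 (13.84 to 14.84) and low in control 10. It was low in the arrays labelled morpholino 1, 2, 3 and 4 (2.68 to 3.06) and high in morpholino 5 (15.07 and 14.82). A further control probe set, named pd2EGFP, stayed between 2.11 and 2.27 in all 20 arrays. Arrays were kept in the groups of their labels throughout. The direction of every comparison that uses controls 6 to 10 or the arrays labelled morpholino is therefore unsettled.

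**Figure D1:**
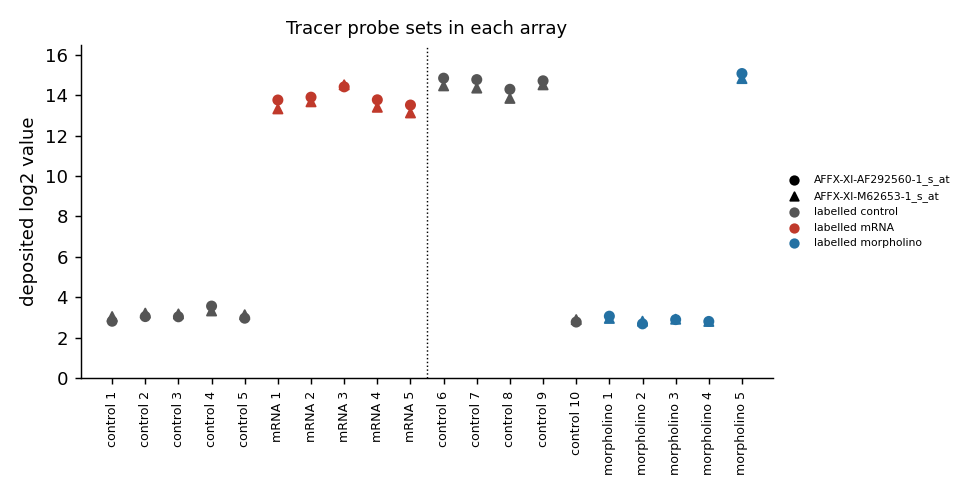
Deposited log2 values of the tracer probe sets (circles, AFFX-Xl-AF292560-1_s_at; triangles, AFFX-Xl-M62653-1_s_at) in each of the 20 arrays, coloured by label; the dotted line parts the first set of arrays from the second. High arrays lie at 13.1 or above and low arrays at 3.56 or below, and 8 arrays right of the line go against their label.

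The gene that was manipulated was measured by 3 probe sets. The rax.L probe set was at 7.10 ± 0.72 (SD, n = 5) in controls 1 to 5 and 4.41 ± 0.88 (SD, n = 5) in mRNA arrays. It fell in the paired fit, by a log2 difference of -2.69 ± 0.29 (limma, adjusted p = 0.0357), and was lower in 5 of 5 pairs. Its call held without pair 5 and not without pair 1 (-2.63), 2 (-2.84), 3 (-2.54) or 4 (-2.46). In the same pairs the rax.S probe set with the higher mean differed by 1.44 ± 0.23 (adjusted p = 0.159) and the other rax.S probe set by -1.37 ± 0.26 (adjusted p = 0.171). Which part of the injected mRNA each rax probe set could detect is not known here. In the second set rax.L was at 5.01, 5.38, 3.78, 4.76 and 6.61 in the arrays labelled control 6 to 10. It was at 6.45, 6.46, 7.10, 7.21 and 3.73 in those labelled morpholino 1 to 5. Against all 10 controls the rax.L difference was -1.70 ± 0.64 (adjusted p = 0.151) for mRNA arrays and 0.09 ± 0.64 (adjusted p = 0.977) for arrays labelled morpholino. The rax.S probe set with the higher mean differed in the opposite direction in mRNA arrays, by 2.41 ± 0.48 (adjusted p = 0.0702), and the other by -0.59 ± 0.44 (adjusted p = 0.459). Between mRNA arrays and those labelled morpholino that first rax.S probe set was called higher by 2.59 ± 0.56 (adjusted p = 0.0156), and was at 0.66 (adjusted p = 0.988) with the array set as a block. Its mean in arrays labelled morpholino, 3.96, lay under log2 4, so the size of this difference is uncertain. The other rax.S probe set (-0.19 ± 0.51, adjusted p = 0.821, and 0.07 without morpholino 3) and rax.L (-1.78 ± 0.73, adjusted p = 0.0987) were not called between these groups. By label, with the array set as a block, rax.L was at -3.77 (adjusted p = 0.589). With 4 control axes added it was at -2.91 (adjusted p = 0.343), or called at -3.77 (adjusted p = 0.0141) with group means removed from the axes. The rax.L difference of arrays labelled morpholino from all controls was -0.17 (adjusted p = 0.933) without control 8. It was -3.28 without the 8 arrays whose tracer went against their label, where morpholino 5 alone stood for its group. That array was at 3.73, under log2 4, so this size is uncertain.

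**Figure D2:**
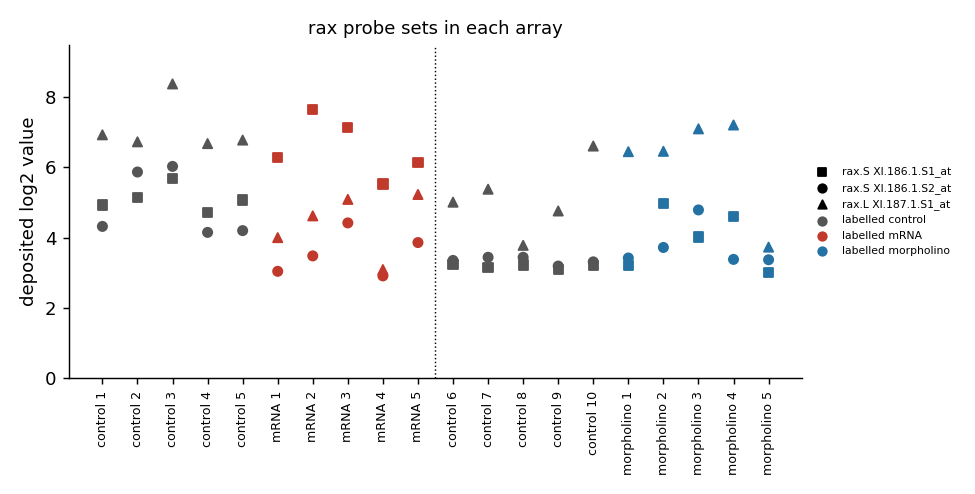
Deposited log2 values of the 3 rax probe sets (squares and circles, rax.S; triangles, rax.L) in each array, coloured by label. The rax.L values of mRNA arrays (3.09 to 5.23) lie below those of controls 1 to 5 (6.68 to 8.38).

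The anterior neural genes hesx1, fezf2.L and pax6.L were lower in mRNA-injected embryos than in the controls of the same number. In the paired fit 7 of 10435 probe sets were called, all lower in 5 of 5 pairs. Both homeologs of hesx1, a homeobox repressor of the anterior neural plate, fell (hesx1.L -2.10 ± 0.22, adjusted p = 0.0357; hesx1.S -2.09 ± 0.19, adjusted p = 0.0248). A pair of probe sets of pax6.L, an eye field transcription factor, fell (-1.18 ± 0.11, adjusted p = 0.0256; -1.08 ± 0.10, adjusted p = 0.0248), and its other 3 were at -0.77 to -1.16 (adjusted p 0.0611 to 0.166). The forebrain zinc finger gene fezf2.L fell (-1.35 ± 0.16, adjusted p = 0.0479), as did rax.L and a probe set without a gene symbol (-2.92 ± 0.26, adjusted p = 0.0248). The mean of that probe set in mRNA arrays, 3.95, lay under log2 4, so the size of its fall is uncertain. Without the number as a block limma called 0 probe sets from these 10 arrays. A fit with all injected arrays against controls 1 to 5 also called 0 (670 at an unadjusted p under 0.05). Without a filter limma called 0 in the paired fit. The count was 0 without pair 1, 2 or 4, it was 5 without pair 3, with 2 of the 7 among them, and it was 2 without pair 5. The 7 stayed lower in each of these fits. Against all 10 controls fezf2.L was at -0.15 (limma, adjusted p = 0.907) and hesx1.S at -1.01 (adjusted p = 0.348). The called pax6.L probe sets were at -0.42 (adjusted p = 0.695) and -0.41 (adjusted p = 0.66). Means in mRNA arrays and controls 6 to 10 were 6.74 and 5.69 for fezf2.L, and 4.32 and 4.25 for hesx1.S. In mRNA arrays the called pax6.L probe sets also lay above controls 6 to 10, while hesx1.L, rax.L and the probe set without a symbol lay below.

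**Figure D3:**
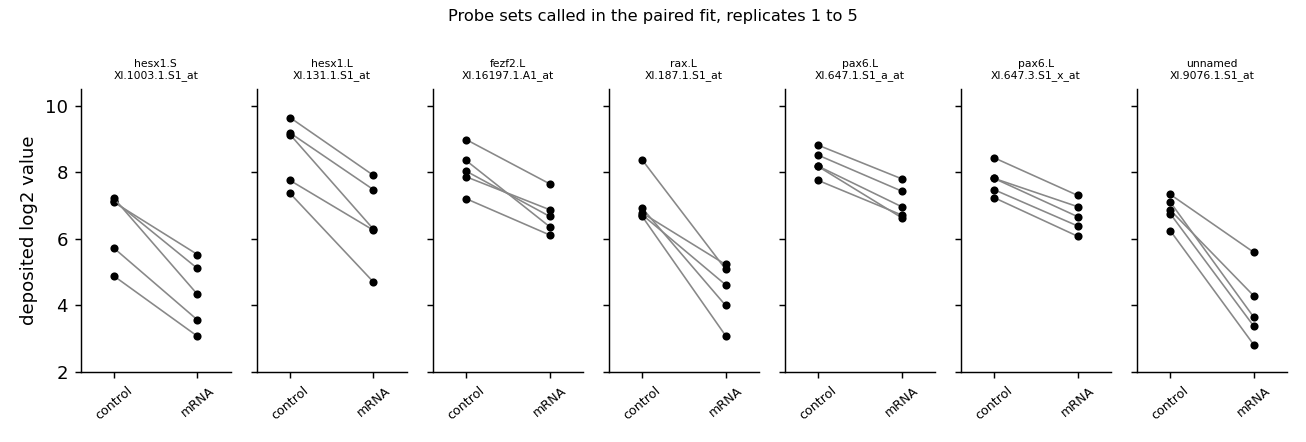
Deposited log2 values of the 7 probe sets called in the paired fit; each line joins an mRNA array to the control array of the same number (1 to 5). All lines go down.

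Eye field, forebrain and other gene groups also differed in the same pairs. Of the 27 lists, 9 passed the threshold with the preset correlation, 3 higher and 6 lower, and 0 did with an estimated correlation. The spread of list means was taken within controls 1 to 5 and 6 to 10, 4 of which carried the tracer signal. That of the eye field list (SD 0.232) exceeded 99.3% of random lists of like size and level. Those of cement gland (0.451) and ribosomal genes (0.115) exceeded 100%, those of FGF and ERK 13.8% and epidermis 38%. Where members vary together, p-values with the preset correlation tend to be too small. The eye field list fell by 0.498 on average over 13 genes (camera, adjusted p = 0.00025), with 11 members below the control mean. Its adjusted p = 0.306 with an estimated correlation. Of its members 1 was called, rax.L of the injected gene itself. Adjusted over the list alone, 1 member was higher, rax.S of the same gene, and 6 were lower, rax.L among them. The array means of the eye field list differed by -0.498, with an exact two-sided permutation p of 0.00794, the smallest 5 against 5 can give, and 0.161 after adjustment over the lists. Flipping signs over the 5 pairs cannot give an exact p under 0.0625. The anterior neural plate and forebrain list fell (mean -0.733, 7 genes, 3 called; adjusted p = 0.0141, and adjusted p = 0.355 with an estimated correlation), its median member being at -0.134. Without the number as a block its adjusted p was 0.0944 from these 10 arrays and 0.045 from a fit with all injected arrays. Its 3 members on the higher side, named after their values were seen, were sp5l.S (0.25 ± 0.12, adjusted p = 0.362), sfrp1.L (0.18 ± 0.21, adjusted p = 0.701) and lhx5.S (0.11 ± 0.20, adjusted p = 0.81, and -0.01 without pair 2 or 4). The cement gland and hatching gland list, from the mucus-secreting organ in front of the neural plate, fell (mean -1.01, 8 of 9 members lower; adjusted p = 1.6e-05, and adjusted p = 0.355 with an estimated correlation). Its 9 measured members were ag1, agr2 and crx with both homeologs each, otx1.L, pitx1.L and cant1.L, so homeologs count apart. The hatching enzyme gene he of the list was not among them. In that list 6 members were lower when adjusted over the list alone and limma called 0 over all genes (6 at an unadjusted p under 0.05). Its secreted disulfide isomerase gene agr2.S was at -2.27 ± 0.31 (adjusted p = 0.0941). The head homeobox gene otx2.L was at -1.05 ± 0.15 (adjusted p = 0.0947) and its other probe set at -2.08 ± 0.42 (adjusted p = 0.205). The organizer homeobox gene gsc.L was at -1.20 ± 0.20 (adjusted p = 0.159). The difference between 3 prime and 5 prime control probe sets of 4 actin and Gapd transcripts, a measure of RNA quality, was 2.68 ± 0.806 (SD, n = 5) in mRNA arrays and 1.64 ± 1.27 (SD, n = 5) in controls 1 to 5. It was higher in mRNA arrays in 3 of 5 pairs (two-sided exact permutation p = 0.175, exact sign-flip p = 0.312).

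The FGF and ERK pathway list rose (mean 0.315, 9 of 12 members higher, 4 when adjusted over the list alone; adjusted p = 0.000796). Its adjusted p = 0.489 with an estimated correlation. Its ligand gene fgf8.L was at 0.66 ± 0.12 (adjusted p = 0.169). The paraxial mesoderm and muscle list rose (mean 0.253, 19 of 26 higher, 5 when adjusted over the list alone; adjusted p = 0.00756). Its adjusted p = 0.495 with an estimated correlation. The myogenic factor gene myod1.S was at 0.54 ± 0.13 (adjusted p = 0.268). The midbrain, hindbrain and posterior neural list rose (mean 0.142, 13 of 17 higher; adjusted p = 0.0333, and adjusted p = 0.355 with an estimated correlation). Without the number as a block its adjusted p was 0.118 from these 10 arrays and 0.0868 from a fit with all injected arrays. Its homeobox gene meis3.S was at 0.50 ± 0.12 (adjusted p = 0.268). The epidermis list fell (mean -0.196, 15 of 24 lower; adjusted p = 0.0262, and adjusted p = 0.495 with an estimated correlation). BMP signalling and ventral genes fell (mean -0.190, 20 of 28 lower; adjusted p = 0.0343, and adjusted p = 0.489 with an estimated correlation). Ribosomal protein genes fell (mean -0.175, 65 of 77 lower; adjusted p = 4.57e-08, and adjusted p = 0.489 with an estimated correlation). The lectin gene itln1.L was at -0.81 ± 0.26 (adjusted p = 0.311), the homeobox gene msx2.L at -0.60 ± 0.18 (adjusted p = 0.3) and the ribosomal rpl4.L at -0.48 ± 0.11 (adjusted p = 0.263). Among control probe sets for bacterial sequences 11 were called in the same pairs, higher in mRNA arrays by 0.36 to 0.61. In size this exceeds the mean of every list in this paragraph, and those that rose went the same way. The eye field mean (-0.498) lies within that range in size.

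The remaining lists did not pass in these pairs. Adjusted p was 0.595 for pan-neural and neural plate progenitor, 0.876 for proneural and neuronal differentiation, 0.322 for the Notch pathway, 0.64 for neural crest and 0.294 for preplacodal ectoderm. It was 0.595 for multiciliated cells, 0.64 for organizer and axial mesoderm, 0.595 for endoderm and 0.312 for blood and endothelium. It was 0.13 for both pluripotency and early embryo and the Wnt pathway, and 0.595 for the Hedgehog pathway, the retinoic acid pathway and p53 targets. It was 0.618 for cell cycle, 0.696 for innate immune response, 0.171 for stress response and 0.5 for genes tied to Rx1 in earlier work. Mean and test differed in sign for the retinoic acid list (mean -0.00572, test direction higher). Mean and median differed in sign for proneural (-0.0163 and 0.146), endoderm (-0.0301 and 0.00253) and blood and endothelium genes (-0.375 and 0.00845). Among members, the neural plate gene zic2.L was at 0.54 ± 0.11 (adjusted p = 0.2) and the neuronal tubulin gene tubb2b.S at -0.74 ± 0.16 (adjusted p = 0.247). The Wnt ligand gene wnt8a.L was at 0.76 ± 0.17 (adjusted p = 0.263) and the early response gene junb.L at 1.00 ± 0.24 (adjusted p = 0.272). The retinoid-binding gene crabp2.L was at -0.89 ± 0.21 (adjusted p = 0.268) and the myeloid factor gene cebpa.L at -1.92 ± 0.31 (adjusted p = 0.159).

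**Figure D4:**
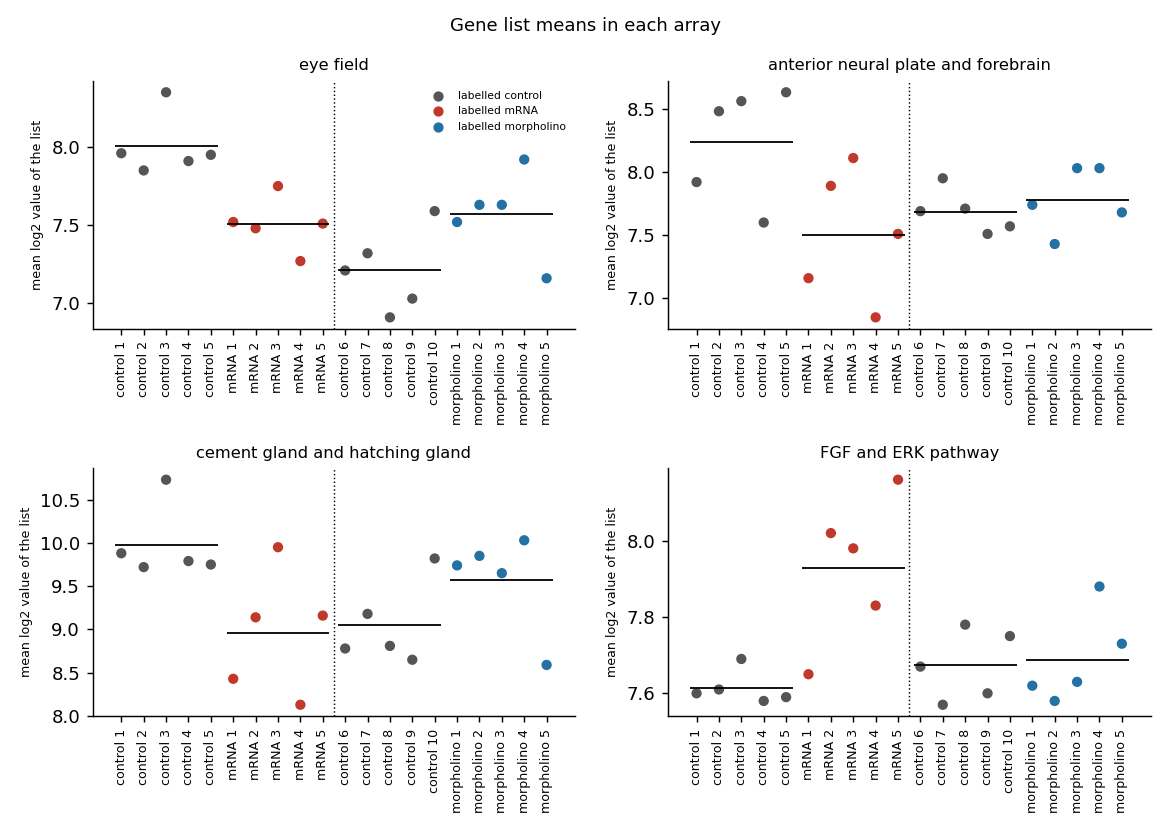
Mean log2 value of the measured genes of 4 lists in each array (points, coloured by label; horizontal lines, means of 5 arrays; the dotted line parts the sets of arrays). In the first set the eye field means of mRNA arrays (7.27 to 7.75) lie below those of controls 1 to 5 (7.85 to 8.35).

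Against all 10 controls, as fixed in advance, no gene passed in mRNA arrays. The head gene otx2.L was closest (-0.98 ± 0.17 and, at its other probe set, -2.02 ± 0.33, both with adjusted p = 0.0569). The ligand gene fgf8.L was at 0.65 ± 0.13 (adjusted p = 0.0702) and the epidermal keratin gene krt12.5.S at -1.46 ± 0.32 (adjusted p = 0.0716). The homeobox genes msx2.L (-0.61 ± 0.15, adjusted p = 0.0813), hesx1.L (-1.88 ± 0.48, adjusted p = 0.082) and gsc.L (-1.17 ± 0.31, adjusted p = 0.0833) did not pass either. The Notch target hes4.S was at 0.63 ± 0.16, rpl3.L at -0.77 ± 0.19 and cebpa.L at -1.95 ± 0.50, each with an adjusted p of 0.082. The neural plate gene zic2.L was at 0.50 ± 0.15 (adjusted p = 0.102), myod1.L at 0.83 ± 0.25 (adjusted p = 0.103) and the ciliary dynein gene dnai1.L at -0.65 ± 0.23 (adjusted p = 0.142). Of 27 lists 7 passed and 0 did with an estimated correlation. Higher were pan-neural and neural plate progenitor and paraxial mesoderm and muscle (both adjusted p = 0.00574, and adjusted p = 0.434 with an estimated correlation). The FGF and ERK pathway was higher (adjusted p = 0.000845, and adjusted p = 0.181 with an estimated correlation). Lower were epidermis (adjusted p = 0.0428), multiciliated cells (adjusted p = 0.0216), BMP signalling and ventral (adjusted p = 0.0428) and ribosomal proteins (adjusted p = 7.25e-14), each with adjusted p = 0.536 with an estimated correlation. Adjusted over the list alone, 4 FGF genes were higher, and 7 epidermis, 3 BMP and 43 ribosomal genes were lower. Against controls 1 to 5 alone without pairing, the fit held all injected arrays. There pan-neural (mean 0.0209, adjusted p = 0.489) and multiciliated cell genes (mean -0.0614, adjusted p = 0.609) did not pass. The other 5 lists did (adjusted p 6.81e-08 to 0.0118, and adjusted p 0.162 to 0.501 with an estimated correlation). These pan-neural and multiciliated lists differed by 0.450 and -0.863 between controls 1 to 5 and controls 6 to 10. limma called 0 probe sets, with 2124 at an unadjusted p under 0.05. The count was 577 without control 1, 314 without control 4, 93 without mRNA 3, 1242 with array weights (360 higher, 882 lower) and 3161 against controls 6 to 10 alone, 4 of which carried the tracer signal. Without mRNA 3, 4 lists passed.

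In arrays labelled morpholino no gene passed against all 10 controls. The endoderm list was lower (mean -0.234, 14 of 18 members lower; adjusted p = 0.0138, and adjusted p = 0.87 with an estimated correlation). Its mean was -0.424 without morpholino 5 (adjusted p = 3.02e-06), the array far from the others of its group, and -0.160 without morpholino 4 (adjusted p = 0.077). Its transcription factor gene gata5.S was at -0.70 ± 0.23 (adjusted p = 0.535). The BMP pseudoreceptor gene bambi.L was at -0.70 ± 0.19, the mesodermal factor foxc2.S at 0.89 ± 0.25 and the neural crest factor zeb2.S at 0.53 ± 0.18, each with an adjusted p of 0.535. limma called 0 probe sets (928 at an unadjusted p under 0.05), and 1 without morpholino 3. It called 1628 against controls 1 to 5, which lie in the other set, and 603 without the 4 controls that carried the tracer signal. With the replicate number as a block it called 2142. Arrays labelled morpholino share their numbers only with controls 1 to 5, so this fit also compares them across the sets. The endoderm mean was -0.185 both with this block and against controls 1 to 5 alone. Without the 8 arrays in doubt, where morpholino 5 alone stood for its group, the endoderm mean was 0.583. No list passed without control 7 or morpholino 2, 3 or 4 (0 lists), 2 passed without control 1, 3, 4 or 10, and 4 without morpholino 5.

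Within the second set, arrays labelled morpholino were set against those labelled control 6 to 10, with 8 of these 10 labels in doubt. The fit also held the mRNA arrays as a group of their own, so their spread enters its p-values. By label, 10 lists passed and 0 did with an estimated correlation. Eye field (mean 0.358) and neural crest genes were higher (both adjusted p = 0.0029, and adjusted p = 0.151 with an estimated correlation). Pan-neural and neural plate progenitor (adjusted p = 0.0247), cement gland and hatching gland (adjusted p = 0.021) and genes tied to Rx1 in earlier work (adjusted p = 0.0029) were higher, each with adjusted p = 0.353 with an estimated correlation. The Hedgehog pathway was higher (adjusted p = 0.0162, and adjusted p = 0.281 with an estimated correlation). Multiciliated cell genes were lower (adjusted p = 0.0482, and adjusted p = 0.353 with an estimated correlation). BMP signalling and ventral (adjusted p = 0.0184) and endoderm (adjusted p = 0.0148) were lower, both with adjusted p = 0.472 with an estimated correlation. Ribosomal protein genes were lower (adjusted p = 0.0029, and adjusted p = 0.662 with an estimated correlation). The Wnt receptor gene fzd3.L was at 0.54 ± 0.21, the eye field gene six3.S at 0.44 ± 0.19 and zeb2.S at 0.61 ± 0.21. The Hedgehog receptor gene smo.L was at 0.42 ± 0.17 and, at its other probe set, 0.10 ± 0.23. The ventral homeobox gene ventx3.2.S was at -0.76 ± 0.20 and the T-box gene vegt.S at -1.29 ± 0.45. Adjusted p was 0.989 for these genes and 1 for that other smo.L probe set. limma called 0 probe sets (426 at an unadjusted p under 0.05). The count of lists was 6 without control 6 or control 9, 2 without morpholino 2 and 5 without morpholino 4.

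Between mRNA arrays and those labelled morpholino 1389 probe sets were called, 503 higher and 886 lower in mRNA arrays, and 595 by at least 2-fold. By label, the naming rule gave mknk2.S, a kinase of the translation factor eIF4E (3.21 ± 0.59, adjusted p = 0.0156), whose other probe set was at 0.61 ± 0.48 (adjusted p = 0.395). The other higher genes had means under log2 4, the level of the filter, in arrays labelled morpholino, so their differences are given as lower bounds with lower values raised to that level. They were at least 1.81 for the pterin synthesis gene pts.L (adjusted p = 0.036), and at least 1.45 for the chromogranin gene chga.S, 1.29 for selenoi.S and 1.82 for adhfe1.S, each with adjusted p = 0.0156. Lower by label were osbpl2.S (-2.97 ± 0.68, adjusted p = 0.0177) and the peptidase gene thop1.L (-2.61 ± 0.83, adjusted p = 0.0429). With means under log2 4 in mRNA arrays, the bounds, which the differences lie at or below, were -2.02 for rdd1.L (adjusted p = 0.0184), -2.34 for pnrc2.L (adjusted p = 0.0177) and -1.08 for the peptidase gene cndp2.S (adjusted p = 0.0231). With the array set as a block none of them was called (adjusted p 0.988 to 0.994): pts.L turned to -0.81 and thop1.L to 0.22. There mknk2.S was at 2.15, chga.S at 0.50, selenoi.S at 0.37, adhfe1.S at 0.89, osbpl2.S at -1.96, rdd1.L at -0.49, pnrc2.L at -0.60 and cndp2.S at -0.63. In a construction with 4 control axes rdd1.L was at 0.03 (adjusted p = 0.989). Without the 8 arrays in doubt only morpholino 5, an array far from the others of its group in several places, stood for its group. There mknk2.S was at 3.78, pnrc2.L at -3.50, cndp2.S at -3.55 and pts.L at 3.01. These sizes are uncertain, since 1 side of each lay under log2 4 (mknk2.S at 3.85 in morpholino 5). Pan-neural and neural plate progenitor genes were higher (adjusted p = 0.0484) and ribosomal protein genes lower (21 of 77 called; adjusted p = 2.18e-09), both with adjusted p = 0.609 with an estimated correlation. With the array set as a block the pan-neural mean turned to -0.145 (adjusted p = 0.374). These groups lie in different sets of arrays. Between controls 1 to 5 and controls 6 to 10, 97.6% of the called probe sets differed with the same sign and 773 were called too (321 for independent lists). With the array set as a block limma called 0 (451 at an unadjusted p under 0.05). The count was 886 without mRNA 1, 455 without mRNA 2, 701 without mRNA 4, 314 without mRNA 5, 523 without morpholino 3 and 737 without morpholino 4. No count is given here without the 8 arrays in doubt. There morpholino 5 alone stands for its group, so nothing is concluded from such a count. The count of lists was 5 without mRNA 1 or morpholino 4, 4 without mRNA 4, and 1 without mRNA 2, 3 or 5 or morpholino 2 or 3.

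Eye field genes also differed within the controls, being higher in controls 1 to 5 than in controls 6 to 10 (mean 0.789, 6 of 13 called; adjusted p = 0.000443, and adjusted p = 0.343 with an estimated correlation). Pan-neural (adjusted p = 0.00119, and adjusted p = 0.343 with an estimated correlation), cement gland (adjusted p = 0.0202, and adjusted p = 0.565 with an estimated correlation) and Rx1-tied genes (adjusted p = 0.0152, and adjusted p = 0.369 with an estimated correlation) were higher too. Multiciliated cell genes were lower (6 of 9 called; adjusted p = 0.00119, and adjusted p = 0.343 with an estimated correlation). Ribosomal protein genes were lower (19 of 77 called; adjusted p = 1.26e-05, and adjusted p = 0.742 with an estimated correlation). Of 10435 probe sets 2414 were called, 880 higher and 1534 lower in controls 1 to 5. Without the 4 controls that carried the tracer signal 52 were called, with control 10 alone in its group.

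No gene was called in both comparisons with all controls, in opposite directions (0) or in the same direction (0). limma gave an unadjusted p under 0.05 in both to 170 probe sets in opposite and 14 in the same direction (99.9 and 89 for independent lists). The log2 differences of the injections correlated at -0.368 across probe sets, which are not independent replicates, against 0.333 for simulated unchanged groups sharing these controls. The covariance was -0.0441 against a simulated 0.0189. That simulation leaves out the sets of arrays. Unchanged groups carrying the observed difference between controls 1 to 5 and controls 6 to 10 gave a simulated correlation of -0.469 and a covariance of -0.0664. The correlation was -0.251 without control 1 and -0.258 without control 4. With each injection set against the controls of its own set it was 0.0106. With these controls crossed it was -0.775, with 1210 probe sets called in opposite directions, and without the 8 arrays in doubt it was -0.0701.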

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

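The tests of the tracer signal, of exchanged labels among the controls, of a response common to both injections, of RNA degradation in the mRNA arrays, of the difference between the injections with the array set as a block, and the paired fit itself were chosen only after the results were seen.

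The signal of the tracer probe sets went against 8 labels. It stood at log2 14.46, 14.35, 13.84 and 14.51 in the arrays labelled control 6, 7, 8 and 9 at AFFX-Xl-M62653-1_s_at, far above controls 1 to 5, in control probe sets the comparisons do not use. Tracer RNA carried into uninjected samples is argued against as the whole cause by the arrays labelled morpholino 1 to 4, which lack the signal (highest 3.06). An embryonic transcript that varies between arrays was not tested, since no table names what these probe sets detect and they were named from the first set, though the name of 1 carries the identifier of a GFP mRNA record. Labels exchanged between the groups may account for it, since 4 arrays labelled morpholino lack the signal and 4 labelled control carry it, but embryos injected or not injected against the plan stay open, and no biological explanation was tested.

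The values of 2414 probe sets differed between controls 1 to 5 and controls 6 to 10, and no biological explanation was tested, since the labels name no parents or spawning. Separate normalization stays open, since quantile normalization of all arrays, after which 2322 differed, cannot remove offsets of single probe sets. Labels exchanged within the second set, as the whole cause, are argued against by the 1628 that differed between controls 1 to 5 and the arrays labelled morpholino. RNA degradation or labelling yield stays open: the difference between 3 prime and 5 prime control probe sets was larger by 0.676 in controls 1 to 5 (exact permutation p = 0.349, 4 transcripts), and these tables cannot decide on it. A batch of arrays or embryos may also underlie the difference and was not tested.

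The eye field list was lower in mRNA arrays than in the controls paired with them. Shared sequence between probe sets of a gene is argued against by the families with homeologs averaged, whose median was -0.368, with 7 of 8 lower. The rax family, that of the injected gene, counts as lower at -0.62, from rax.L at -2.69 and rax.S at 1.44. A response to injection or tracer common to both injections cannot be told apart from one to Xrx1: the difference between the injections by label had an adjusted p of 0.0123 with an estimated correlation, but 8 labels behind it are in doubt. RNA degradation or labelling yield stays open as a part of the cause: the difference between 3 prime and 5 prime control probe sets was larger by 1.04 in mRNA arrays (exact permutation p = 0.175), higher in 3 of 5 pairs. It was not larger in pair 1 (2.50 against 3.00) or pair 4 (2.94 against 2.96). The eye field mean still fell there (7.52 against 7.96, and 7.27 against 7.91), which argues against degradation as the whole cause in those pairs. An effect of excess Xrx1, which the design names, stays open and was not tested apart from these.

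By label, 9 lists moved differently after the injections, each against the controls of its own set, in a test of that difference with the preset correlation. Adjusted p was 9.21e-08 for eye field, 0.0352 for anterior neural plate and forebrain, 0.0476 for midbrain, hindbrain and posterior neural, 0.0193 for neural crest and 7.18e-06 for cement gland and hatching gland. It was 0.0281 for both paraxial mesoderm and muscle and the FGF and ERK pathway, 0.0476 for ribosomal proteins and 0.0193 for genes tied to Rx1 in earlier work. The Rx1-tied list shares otx2, pax6 and six3 with eye field, so these 9 lists are not separate evidence. Eye field alone passed with an estimated correlation. The direction rests on labels that the tracer contradicts in 8 arrays.

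Single arrays lay far from the others of their group in 22 places, where chance gives such a gap in about 1 in 20 groups. In all, 216 groups of values were tested, and 19 of the 22 were among named genes and lists. The array labelled morpholino 5 was low for rax.L (3.73), pax6.L (4.41 and 4.83), agr2.S (6.52), agr2.L (5.82) and the probe set without a symbol called in the paired fit (4.04). It was also far from the others of its group in the list means of paraxial mesoderm and muscle (7.51), endoderm (7.86), cement gland and hatching gland (8.59) and Hedgehog pathway (6.07), and high in the tracer probe sets (15.07 and 14.82). At AFFX-Xl-a3Act-3_s_at, a control probe set for an actin, it was at 2.79 against 7.57 to 11.12 in the other 19 arrays. The others were rax.S in morpholino 3 (4.79), otx2.L in morpholino 4 (8.82), otx2.S in morpholino 1 (5.12), zic2.L in control 7 (9.99), itln1.L in morpholino 2 (13.68) and zeb2.S in morpholino 4 (9.63). The remaining ones were mknk2.S in morpholino 3 (6.95), selenoi.S in morpholino 1 (2.68) and thop1.L in morpholino 2 (4.51).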

How the results depend on the processing

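The paired fit, the set block, the 4 control axes and all fits without arrays in doubt were alternatives chosen after seeing the data. The cause was not tested for any result that moved or reversed below, apart from what an alternative itself removes.

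For mRNA against control, where 0 probe sets were called, the count was 6 with the filter at log2 6, 20 with a variance trend and robust fitting, 1242 with array weights (360 higher, 882 lower), 3161 against controls 6 to 10 and 7 in the paired fit. Leaving out 1 array gave 0 to 577. For arrays labelled morpholino against control, again 0, it was 2142 with the replicate block, 1628 against controls 1 to 5, 603 without the 4 controls with tracer signal and 495 without the 8 arrays in doubt. Leaving out 1 array gave 0 or 1. The 1389 between the injections became 2186 with no filter, 772 with the filter at log2 6, 2851 with array weights, 2885 with the replicate block, 0 with the set block (limma, 451 at an unadjusted p under 0.05) and 760 without the 8 arrays. Leaving out 1 array gave 314 to 1327. The counts without the 8 arrays rest on morpholino 5 alone in its group, so nothing is concluded from them.

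With the set block and 4 axes of variation among controls the count depended on how the axes were built, both ways taking them from control arrays under test. It was 5 for mRNA against control and 2 between the injections, or 103 and 24 with group means removed from the axes.

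The 7 calls of the paired fit became 0 without the block, 0 with no filter and 0 with the set block on all arrays. In a fit with all injected arrays and no block, limma gave 670 an unadjusted p under 0.05. Leaving out 1 pair gave 0 to 5. Quantile normalization and median centring kept the same 7, a variance trend called 8 with the 7 among them, and the filter at log2 6 called 8 with 6 of the 7. Arrays labelled morpholino against controls 6 to 10 gave 23 without the 8 arrays, from lone arrays in both groups. Between the groups of controls 2414 became 3828 with no filter and 52 without the 4 controls.

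The correlation of the injections, -0.368, reversed to 0.0106 within sets. It was 0.102 with the replicate block, which sets both injections against the same controls of the first set. Unchanged groups sharing all controls gave 0.333 in simulation, so nothing is concluded from the sign of 0.102. The correlation was -0.775 with controls crossed, with 1210 probe sets called in opposite directions. It was -0.0701 without the 8 arrays, and -0.431 to -0.251 with 1 array left out.

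With an estimated correlation 0 lists passed in each comparison, except that the eye field list did (adjusted p = 0.0123) for the difference between the injections with the set block. Lists past for mRNA against control were 4 against controls 6 to 10 and 4 to 8 with 1 array left out. For arrays labelled morpholino against control they were 2 with the mean of all probe sets or no filter, 3 with the replicate block, controls 1 to 5 or without the 4 controls, 10 with controls 6 to 10 or the set block, 0 without the 8 arrays, and 0 to 4 with 1 array left out. Between the injections they were 4 with the mean of all probe sets or quantile normalization, 9 with the set block and 1 to 5 with 1 array left out. Within the second set leaving out 1 array gave 2 to 10. The endoderm mean of arrays labelled morpholino reversed to 0.583 without the 8 arrays, and the pan-neural mean between the injections to -0.145 with the set block. The eye field mean in the paired fit stayed between -0.671 and -0.413 over 10 settings, each pair left out among them (adjusted p 7.26e-06 to 0.306, at most 0.00271 apart from the estimated correlation). Of the other lists past in that fit, midbrain, hindbrain and posterior neural lost its call without the block (adjusted p = 0.118), with no filter (0.113), with quantile normalization (0.0535) and without pair 1 (0.108), 4 (0.0834) or 5 (0.0502). The anterior neural plate and forebrain list lost it without the block (0.0944) or pair 1 (0.0712), and epidermis with quantile normalization (0.0535) or without pair 3 (0.152). BMP signalling and ventral lost it without pair 3 (0.149) or 4 (0.148).

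In mRNA against control, rax.L passed at -1.84 with array weights (adjusted p = 0.0315), -2.69 in the paired fit (adjusted p = 0.0357) and -2.69 with 4 axes and group means removed (adjusted p = 0.0104). In arrays labelled morpholino against control, rax.L reversed to -0.91 with the replicate block or controls 1 to 5, -0.83 without the 4 controls, -3.28 without the 8 arrays and -0.17 without control 8 (up to 0.70 without morpholino 5). Without the 8 arrays it also reversed between the injections (0.67) and within the second set (-2.88). The rax.S probe set with the higher mean reversed to 0.78 against controls 6 to 10, with the set block and with 4 axes and group means removed, and to 0.68 with the other axes. It was -0.44 without morpholino 2, 0.05 without morpholino 5, and -0.20 within the second set without the 8 arrays. The other rax.S probe set reversed to 0.19 in mRNA arrays against controls 6 to 10. In arrays labelled morpholino it reversed to 0.39 against controls 6 to 10, with the set block and with 4 axes and group means removed, and to 0.32 with the other axes. Between the injections it reversed to 0.17 without the 8 arrays and ran from -0.41 without mRNA 3 to 0.07 without morpholino 3.

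In the paired fit lhx5.S reversed to -0.01 without pair 2 or 4 (0.28 without pair 1). Within the second set without the 8 arrays fzd3.L (-0.25), six3.S (-0.06), ventx3.2.S (0.16) and vegt.S (1.72) reversed. Between the injections pts.L reversed with the set block (-0.81) and with 4 axes (-0.76 and -0.81), thop1.L with the set block (0.22) and 4 axes (0.57 and 0.22), and rdd1.L with 4 axes (0.03). Probe sets near background limit what these arrays can show: the filter left 10435 of 15491.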

Other observations

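The tests of other splits within the first and within the second set were chosen only after other splits had been seen, and the other tests of splits were chosen before.

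Other splits of the same arrays into groups of the same sizes were fitted alike, at most 100 for each comparison. Chance can be excluded for the 1389 probe sets between the injections (1 of 100 splits gave as many, the real one; highest other 4) and for the 2414 between the groups of controls (1 of 100; highest other 16). Both of these splits also follow the sets of arrays. Where the real count is 0 every split reaches it, so the splits say nothing of chance: mRNA against control (100 of 100; highest other 623) and arrays labelled morpholino against control (100 of 100; highest other 325; limma, 2124 and 928 at an unadjusted p under 0.05). Chance cannot be excluded for mRNA against control, where 2124 had an unadjusted p under 0.05 (6 of 100; highest other 2874) and 7 lists passed (10 of 100; highest other 12). These splits mix the sets of arrays and break the pairs. Splits within the first set do not exclude chance for the 670 at an unadjusted limma p under 0.05 against controls 1 to 5 (17 of 100, highest other 2349). For the 8 lists there, 3 of 100 splits gave as many (highest other 10). These splits still break the pairs and were chosen after others had been seen, so chance is not taken as excluded. By splits over both sets it cannot be excluded for arrays labelled morpholino against control, with 928 at an unadjusted p under 0.05 (21 of 100; highest other 2514) and 1 list (78 of 100; highest other 10). It cannot be excluded for the 2 lists between the injections (71 of 100; highest other 10). In the paired fit the 16 sign patterns are too few for a share under 0.05: the real one gave 7 probe sets (1 of 16; highest other 0) and 9 lists (2 of 16; highest other 9).

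Within the second set limma called 0 probe sets by label (426 at an unadjusted p under 0.05), which 100 of 100 splits must reach and so says nothing of chance, and 10 lists passed (5 of 100; highest other 12), for which chance cannot be excluded. The highest other split called 291 probe sets, and the next 34. It puts the arrays labelled control 6, 7, 8, 9 and morpholino 5 on one side and control 10 with morpholino 1, 2, 3 and 4 on the other, which is also how the tracer signal parts them. It points to a structure of the samples. The arrays were not regrouped, and no gene or direction is drawn from that split.

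The 120 control probe sets were left out of every count. Tested apart with limma, 13 of them were called in the paired fit, the tracer probe sets included, and 13 between controls 1 to 5 and controls 6 to 10. The other 11 called in the paired fit are probe sets for bacterial sequences, and all 11 were higher in mRNA arrays, by 0.36 to 0.61 on the log2 scale. The 7 gene probe sets called in that fit were lower, by a log2 difference of -1.08 to -2.92. No alternative corrects a shift of such controls against embryo RNA.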
